A study of Homo sapiens with 24 samples.

How the data were processed

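RNA sequencing was done on 24 libraries of HEL cells, from 12 combinations of treatment (DMSO or 500 nM of 5 JAK inhibitors) and time (4 h or 48 h), with 2 libraries each. Per the submitters' processing notes, reads were converted with bcl2fastq, aligned with STAR 2.5.1a to GRCh38 and processed with edgeR. The authors deposited 1 table of read counts per gene, whose values are whole numbers. The counting tool, the gene annotation and the strandedness are not given in the sources used here. The table held 34343 entries, of which 130 repeated an Ensembl ID, leaving 34213 genes. Its identifiers end at ENSG00000278857, and genes with higher identifiers are not analysed here. Symbols came from the deposited table and coordinates from GENCODE 29, which held 34209 of the genes.

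Genes were tested with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Low counts were filtered with filterByExpr, which left 16076 genes, and libraries were scaled with TMM. A quasi-likelihood model with 1 mean per group was fitted to all 24 libraries. It had 12 residual degrees of freedom, a median of 19.4 prior degrees of freedom and a common biological coefficient of variation of 0.0468. P-values were adjusted over all tested genes by the method of Benjamini and Hochberg, and an adjusted p under 0.05 was called. The SE of a log2 fold change was its absolute value divided by the square root of the F statistic. Each inhibitor was compared with DMSO at the same time, the inhibitors with each other, DMSO at 48 h with DMSO at 4 h, and the change against DMSO between the times, in 38 named comparisons. The comparisons, the alternatives, the 20 gene lists and the rule for naming genes were set before the data were examined.

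Lists of genes (466 members written) were tested with camera, with a preset correlation between genes of 0.01 and again with a correlation estimated for each list. Counts of list members are given after adjustment over all genes and adjusted over the list alone. A gene could be named if it was 1 of 15 chosen in advance (JAK2, PIM1, CISH, SOCS2, SOCS3, MYC, BCL2L1, ID1, DUSP6, CCND2, HEXIM1, HMGCS1 and HBG2, with 2 others not reported here), 1 of the 6 most changed genes per direction with a mean log2 CPM of at least 3 and no overlap between the libraries compared, or 1 of up to 4 called members of a list. Of the genes this rule allows, those printed in the text were picked after the values were seen, and the values of the rest were written to the result tables. CPM are counts scaled to library size. For the ERK list with ruxolitinib at 48 h the text gives the mean of the members in place of the median.

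The alternatives were DESeq2 1.42.0, scaling by RLE, no low-count filter, a stricter filter (1 CPM in 6 libraries), the libraries of 1 time point only, the replicate number as a block, and each library left out in turn. When a library was left out, the lone library of its group was assumed to vary like the other groups. Further alternatives, protein-coding genes only and another DMSO library for each inhibitor of a pair, were chosen after seeing the data. Overlap between inhibitors was compared with 20 simulations in which the comparisons shared a control and had no effect.

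The tests were tested on simulated data made from the comparison of ruxolitinib with DMSO at 4 h. Both edgeR and DESeq2 recovered 44.8% of 67 genes changed by a factor 25% above 1 and 82.1% of 67 changed by a factor 50% above 1. Of 66 genes changed 2-fold, edgeR recovered 89.4% and DESeq2 87.9%. Of 171 edgeR calls over all simulated sizes 9 were false, and 0 genes were called where nothing was changed. Total counts per library were 32153866 to 56618281. The 2 libraries of each group were not duplicates by a chi-square check, and pairs across groups were not checked. The 2 leading principal components held 11.7% and 10.7% of the variance.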

Results

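Gene expression was measured by RNA sequencing in HEL cells, an erythroleukaemia line that carries an activating JAK2 mutation. Cells received DMSO, the solvent control, or 1 of 5 JAK inhibitors at 500 nM: ruxolitinib, fedratinib, momelotinib, pacritinib or itacitinib. They were collected after 4 h or 48 h. Each of the 12 combinations of treatment and time had 2 libraries, 24 in all, so every value given for a group rests on n = 2. After 4 h, the total counts of replicates 1 and 2 were 33039413 and 45550784 with DMSO, 32153866 and 38866651 with ruxolitinib, and 37789623 and 45630743 with fedratinib. They were 37757276 and 44022735 with momelotinib, 40639905 and 42147566 with pacritinib, and 35189655 and 37790343 with itacitinib. After 48 h, they were 36232962 and 36251895 with DMSO, 35828073 and 33484457 with ruxolitinib, and 35529095 and 39581506 with fedratinib. For momelotinib they were 35417398 and 39105677, for pacritinib 32621857 and 37759745, and for itacitinib 45942802 and 56618281. The labels do not say whether replicates were separate cultures. The p-values measure only the spread between these libraries, which may be technical.

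In GRCh38 coordinates (GENCODE 29), the genes that recur across comparisons were JAK2 (ENSG00000096968) on chromosome 9 from 4984390 to 5128183, PIM1 (ENSG00000137193) on chromosome 6 from 37170203 to 37175426, CISH (ENSG00000114737) on chromosome 3 from 50606490 to 50611831, and DUSP6 (ENSG00000139318) on chromosome 12 from 89347232 to 89353271. Genes that set an inhibitor or a time apart included HEXIM1 (ENSG00000186834) on chromosome 17 from 45148502 to 45152101, ID3 (ENSG00000117318) on chromosome 1 from 23557918 to 23559794, HBZ (ENSG00000130656) on chromosome 16 from 152687 to 154503, and MT-RNR1 (ENSG00000211459) on the mitochondrial genome from 648 to 1601. Reads of near-identical genes, such as HBA1 and HBA2, the histone genes and RN7SL copies, can be assigned to either copy, so their single values are uncertain.

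Some RNAs that can vary with RNA quality and library preparation moved with the groups. The mitochondrial rRNA genes MT-RNR1 and MT-RNR2 took 0.0181 and 0.00715% of counts in the DMSO libraries at 4 h. Their share was 0.0604 and 0.0611% with ruxolitinib and 0.0141 and 0.0191% with pacritinib at 4 h, and 0.0586 and 0.0912% with DMSO at 48 h. RN7SL copies, for the RNA of the signal recognition particle, took 2.42 and 2.52% with DMSO at 4 h and 2.80 to 3.98% with the inhibitors. At 48 h they took 3.05 and 3.36% with DMSO and 3.10 to 4.76% with the inhibitors, with the highest shares for fedratinib (4.67 and 4.42%) and pacritinib (4.52 and 4.76%).

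**Figure D1:**
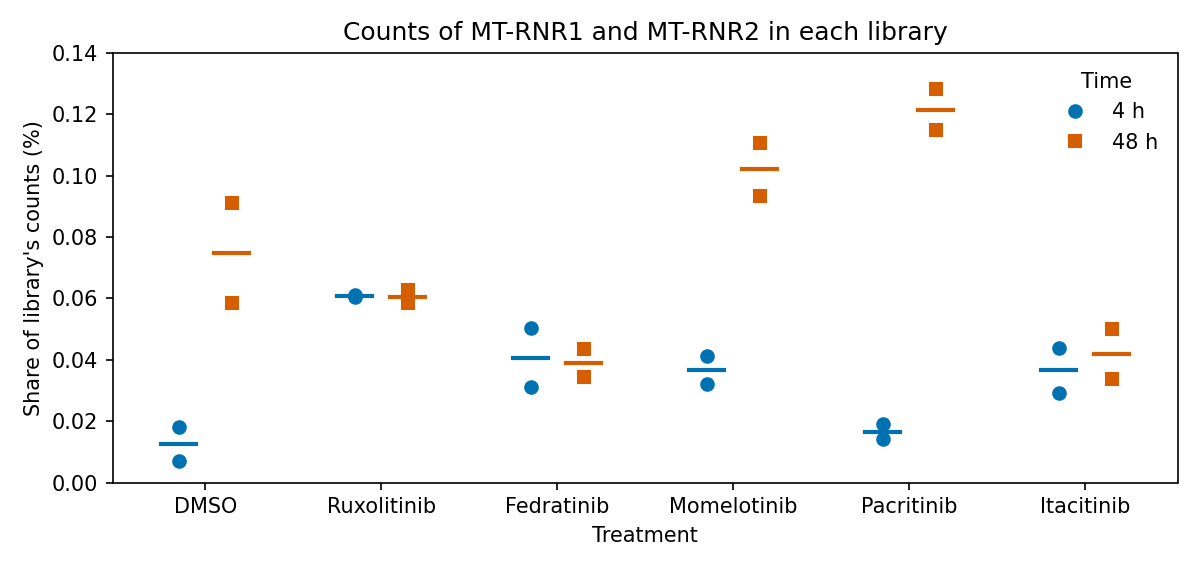
Share of all counts in each library that came from MT-RNR1 and MT-RNR2 (percent), by treatment and time, with the mean of the 2 libraries as a line. DMSO at 4 h lay at 0.0181 and 0.00715%, and the inhibitor libraries at 4 h between 0.0141% and 0.0611%.

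The series is titled as a profile of JAK inhibitors in clinical use, and each was compared with DMSO at the same time to ask which genes it changed. By 4 h, ruxolitinib had lowered the feedback inhibitors that JAK-STAT signalling induces, SOCS3 (-2.61 ± 0.15), SOCS1 (-2.10 ± 0.18), CISH (-1.76 ± 0.08) and SOCS2 (-0.53 ± 0.08) (log2 fold change ± SE). The PIM kinases fell with them (PIM1 (-1.69 ± 0.06) and PIM2 (-2.09 ± 0.06)), and so did the ERK outputs DUSP6 (-2.73 ± 0.15), EGR1 (-2.40 ± 0.14) and PHLDA1 (-1.79 ± 0.12). Genes for survival proteins were lower, BCL2 (-1.01 ± 0.11), BCL2L1 (-0.87 ± 0.05) and MCL1 (-0.34 ± 0.05). Other genes with large decreases were BCL3 (-2.32 ± 0.16), IL21R (-2.28 ± 0.12), APOL4 (-2.04 ± 0.15) and ID1 (-1.98 ± 0.08). Among genes with a mean log2 CPM of at least 3 and no overlap between libraries, the largest increases were in MT-RNR1 (2.55 ± 0.30), MT-RNR2 (2.20 ± 0.25) and ST8SIA1 (1.05 ± 0.12). JAK2 was higher (0.27 ± 0.05), whereas CCND2 was lower (-0.30 ± 0.05). HEXIM1 was not called (0.08 ± 0.06, adjusted p = 0.483). MYC (-0.16 ± 0.04) lost its call without DMSO replicate 2 (adjusted p = 0.0505) and without ruxolitinib replicate 2 (adjusted p = 0.0766). By edgeR, 550 genes were higher and 811 lower than in DMSO, and 24 of the higher and 76 of the lower genes changed at least 2-fold. The total of 1361 became 883 without DMSO replicate 1, 730 without DMSO replicate 2, 761 without ruxolitinib replicate 1 and 776 without ruxolitinib replicate 2.

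Of the gene lists, 20 of the 23 JAK-STAT target genes were lower and 0 higher (21 and 1 adjusted over the list alone). Their median was -0.53 (list adjusted p = 1.25e-108, and adjusted p = 4.57e-07 with an estimated correlation). 16 of the 18 ERK pathway output genes were lower and 0 higher (16 and 0 adjusted over the list alone). Their median was -1.08 (list adjusted p = 1.01e-59, and adjusted p = 1.51e-05 with an estimated correlation). In the erythroid list, 12 of 33 genes were higher and 0 lower (19 and 1 adjusted over the list alone, median 0.19, adjusted p = 0.0175 with an estimated correlation). In the BCL2 family list, 5 of 15 genes were lower and 0 higher (5 and 1 adjusted over the list alone, median -0.10, adjusted p = 0.00269 with an estimated correlation). In the NF-kB target list, 3 of 18 genes were lower (5 adjusted over the list alone, median -0.17, adjusted p = 0.0175 with an estimated correlation). In the ribosome biogenesis list, 11 of 28 genes were lower (14 adjusted over the list alone, median -0.13, adjusted p = 0.0217 with an estimated correlation). In the mitosis list, 3 of 26 genes were higher (4 adjusted over the list alone, median 0.09, adjusted p = 0.0376 with an estimated correlation). The ATF4 stress response, p53 target and cholesterol synthesis lists were lower with the preset correlation only, with medians of -0.13, -0.09 and -0.14 (adjusted p = 0.065, 0.086 and 0.0873 with an estimated correlation). The BET-raised list was higher (median 0.08, adjusted p = 0.316 with an estimated correlation), but not without DMSO replicate 2 (adjusted p = 0.0659) or ruxolitinib replicate 1 (adjusted p = 0.146). The mitochondrially encoded list was higher with the preset correlation (median 0.18, adjusted p = 0.414 with an estimated correlation), while without DMSO replicate 2 its median was -0.09 (adjusted p = 0.592). The megakaryocyte and platelet list had a median of 0.05 and a mean of -0.04, and its test pointed down (adjusted p = 0.0829 with an estimated correlation). Platelet genes went both ways, with GP6 (-1.51 ± 0.09) and MMRN1 (-0.65 ± 0.07) lower and TUBB1 (0.63 ± 0.10) higher, and without ruxolitinib replicate 2 the call ended (adjusted p = 0.057). The other 7 lists did not pass (adjusted p = 0.0546 to 0.922). Of the 26 JAK, STAT and receptor genes, 5 were higher and 6 lower (5 and 8 adjusted over the list alone), the latter with IL4R (-1.30 ± 0.11) and SH2B3 (-0.68 ± 0.05).

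Fedratinib changed few genes at 4 h, and by little. It lowered PIM2 (-0.35 ± 0.06), BCL3 (-0.80 ± 0.13) and IL21R (-0.62 ± 0.10) and the platelet genes GP6 (-0.45 ± 0.08) and TBXA2R (-0.62 ± 0.08). The sestrin genes SESN3 (0.69 ± 0.09) and SESN2 (0.40 ± 0.06) were higher, beside MT-RNR1 (2.00 ± 0.30) and MT-RNR2 (1.57 ± 0.24). The JAK-STAT targets SOCS1 (-0.60 ± 0.16), BCL2L1 (-0.22 ± 0.04) and ID1 (-0.29 ± 0.07) and the ERK outputs PHLDA1 (-0.42 ± 0.11), FOSL1 (-0.38 ± 0.08) and ETV5 (-0.37 ± 0.07) were lower, but each kept its call in at most 1 of the 4 fits with a library left out (adjusted p = 0.0509 to 0.306 in the others). Not called were PIM1 (-0.16 ± 0.05, adjusted p = 0.145), CISH (-0.19 ± 0.07, adjusted p = 0.198), SOCS3 (-0.42 ± 0.12, adjusted p = 0.0681) and DUSP6 (0.11 ± 0.11, adjusted p = 0.748). By edgeR, 99 genes were higher and 156 lower than in DMSO, with 6 and 1 changed at least 2-fold. The total of 255 became 154 without DMSO replicate 1, 39 without DMSO replicate 2, 61 without fedratinib replicate 1 and 63 without fedratinib replicate 2. In the JAK-STAT target list, 5 of 23 genes were lower (10 adjusted over the list alone, median -0.15, adjusted p = 0.0247 with an estimated correlation). In the ribosome biogenesis list, 5 of 28 genes were lower (17 adjusted over the list alone, median -0.15, adjusted p = 0.0102 with an estimated correlation). The ATF4 stress response list was higher with the preset correlation only, with a median of 0.17 (adjusted p = 0.0599 with an estimated correlation). Also with it only, the megakaryocyte and platelet, ERK pathway output, cholesterol synthesis and NF-kB target lists were lower, with medians of -0.09, -0.18, -0.07 and -0.11 (adjusted p = 0.0644, 0.209, 0.179 and 0.209 with an estimated correlation). Single libraries ended the megakaryocyte (fedratinib replicate 1, adjusted p = 0.0539), ERK (fedratinib replicate 2, adjusted p = 0.0557) and NF-kB calls (DMSO replicate 2, adjusted p = 0.0943, and fedratinib replicate 1, adjusted p = 0.185). The other 13 lists did not pass (adjusted p = 0.162 to 0.98).

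Momelotinib at 4 h lowered JAK-STAT targets and ERK outputs. JAK-STAT feedback genes and kinases were down, with SOCS1 (-1.24 ± 0.17), SOCS3 (-1.04 ± 0.13), PIM2 (-0.94 ± 0.06) and PIM1 (-0.35 ± 0.05), and so were the ERK outputs DUSP6 (-1.24 ± 0.12), EGR1 (-1.23 ± 0.12) and DUSP5 (-0.93 ± 0.14). The survival genes BCL2 (-0.75 ± 0.11) and BCL2L1 (-0.58 ± 0.04) were lower. Among the largest changes, BCL3 (-1.65 ± 0.14), IL21R (-1.65 ± 0.11), GP6 (-1.07 ± 0.08) and PLCH1 (-1.09 ± 0.07) were lower and MT-RNR1 (1.72 ± 0.30), MT-RNR2 (1.53 ± 0.24) and ST8SIA1 (0.90 ± 0.12) higher. CISH was lower (-0.34 ± 0.07), but not without DMSO replicate 2 (adjusted p = 0.251). JAK2 (0.25 ± 0.05) lost its call without DMSO replicate 2 (adjusted p = 0.0768) and without momelotinib replicate 2 (adjusted p = 0.143). MYC (-0.16 ± 0.04) lost its call without DMSO replicate 1 (adjusted p = 0.0638), without DMSO replicate 2 (adjusted p = 0.0868) and without momelotinib replicate 2 (adjusted p = 0.121). HEXIM1 (-0.26 ± 0.06) lost its call without DMSO replicate 2 (adjusted p = 0.0684). HMGCS1 (-0.25 ± 0.06) lost its call without DMSO replicate 1 (adjusted p = 0.0564) and without momelotinib replicate 1 (adjusted p = 0.0726). CCND2 (-0.17 ± 0.05) lost its call without DMSO replicate 1 (adjusted p = 0.129), without DMSO replicate 2 (adjusted p = 0.187) and without momelotinib replicate 1 (adjusted p = 0.345). By edgeR, 356 genes were higher and 609 lower than in DMSO, and 12 of the higher and 34 of the lower genes changed at least 2-fold. The total of 965 became 567 without DMSO replicate 1 and 453 without DMSO replicate 2. Of the lists, 16 of the 23 JAK-STAT target genes were lower and 0 higher (19 and 0 adjusted over the list alone). Their median was -0.30 (list adjusted p = 1.05e-41, and adjusted p = 8.1e-05 with an estimated correlation). 15 of the 18 ERK pathway output genes were lower and 0 higher (16 and 0 adjusted over the list alone). Their median was -0.86 (list adjusted p = 4.42e-42, and adjusted p = 8.1e-05 with an estimated correlation). In the erythroid list, 8 of 33 genes were higher (10 adjusted over the list alone, median 0.15, adjusted p = 0.0243 with an estimated correlation). In the mitosis list, 6 of 26 genes were lower (11 adjusted over the list alone, median -0.12, adjusted p = 0.017 with an estimated correlation). In the cholesterol synthesis list, 6 of 24 genes were lower (11 adjusted over the list alone, median -0.15, adjusted p = 0.0241 with an estimated correlation). In the ribosome biogenesis list, 4 of 28 genes were lower (5 adjusted over the list alone, median -0.10, adjusted p = 0.0241 with an estimated correlation). In the NF-kB target list, 3 of 18 genes were lower (4 adjusted over the list alone, median -0.21, adjusted p = 0.017 with an estimated correlation). In the BCL2 family list, 4 of 15 genes were lower and 0 higher (5 and 1 adjusted over the list alone, median -0.00, adjusted p = 0.0149 with an estimated correlation). In the BMP-SMAD target list, 2 of 9 genes were lower (2 adjusted over the list alone, median -0.28, adjusted p = 0.0422 with an estimated correlation). The BMP-SMAD call ended without the low-count filter (adjusted p = 0.149). In the megakaryocyte and platelet list, 8 of 26 genes were lower and 2 higher (8 and 3 adjusted over the list alone, median -0.02, adjusted p = 0.0173 with an estimated correlation). The p53 target list was lower with the preset correlation only, with a median of -0.08 (adjusted p = 0.122 with an estimated correlation). The other 9 lists did not pass (adjusted p = 0.208 to 0.715).

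Pacritinib changed more genes at 4 h than any other inhibitor did. It lowered the inhibitors of differentiation that BMP-SMAD signalling drives, ID3 (-2.02 ± 0.13), ID2 (-1.53 ± 0.12) and ID1 (-1.06 ± 0.08), and HEXIM1, which restrains transcription elongation (-1.78 ± 0.06). JAK-STAT feedback genes fell, SOCS1 (-1.77 ± 0.17), SOCS3 (-1.22 ± 0.13), CISH (-0.57 ± 0.08) and SOCS2 (-0.69 ± 0.08), and so did the ERK outputs PHLDA1 (-2.04 ± 0.12), DUSP4 (-1.80 ± 0.38) and DUSP6 (-1.58 ± 0.13). Chemokines and other NF-kB targets were lower, led by CXCL8 (-3.32 ± 0.44), BCL3 (-2.07 ± 0.15) and CXCL3 (-1.11 ± 0.16). The cyclins CCNE2 (-1.10 ± 0.12) and CCNE1 (-0.75 ± 0.09) and the p53 target CDKN1A (-1.11 ± 0.18) fell too. The globin genes HBD (1.31 ± 0.14) and HBG2 (0.26 ± 0.06) and the sterol gene MSMO1 (0.52 ± 0.11) were up. Their lists did not hold with an estimated correlation (adjusted p = 0.0804 and 0.385). Among genes with a mean log2 CPM of at least 3 and no overlap between libraries, the largest increases were MS4A2 (1.67 ± 0.11), ST8SIA1 (1.24 ± 0.12), SEC31B (1.23 ± 0.12) and DNHD1 (1.16 ± 0.09), and IL21R (-2.12 ± 0.12) and BCL2L1 (-0.65 ± 0.04) were lower. PIM1 was lower by less than with ruxolitinib (-0.25 ± 0.05), a call lost without pacritinib replicate 2 (adjusted p = 0.0831). Neither JAK2 (0.03 ± 0.05, adjusted p = 0.731) nor MYC (-0.00 ± 0.04, adjusted p = 0.976) was called. By edgeR, 2109 genes were higher and 2805 lower than in DMSO, and 282 of the higher and 254 of the lower genes changed at least 2-fold. The total of 4914 became 3237 without pacritinib replicate 2.

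With pacritinib at 4 h, 17 of the 18 ERK pathway output genes were lower and 0 higher (17 and 0 adjusted over the list alone). Their median was -0.90 (list adjusted p = 4.15e-21, and adjusted p = 0.00202 with an estimated correlation). 18 of the 23 JAK-STAT target genes were lower and 0 higher (18 and 0 adjusted over the list alone). Their median was -0.55 (list adjusted p = 4.25e-20, and adjusted p = 0.00202 with an estimated correlation). In the BMP-SMAD target list, 4 of 9 genes were lower (4 adjusted over the list alone, median -0.31, adjusted p = 0.00666 with an estimated correlation). In the NF-kB target list, 12 of 18 genes were lower and 0 higher (13 and 1 adjusted over the list alone, median -0.50, adjusted p = 0.0145 with an estimated correlation). The erythroid and cholesterol synthesis lists were higher with the preset correlation only, with medians of 0.21 and 0.04 (adjusted p = 0.0804 and 0.385 with an estimated correlation). On the same terms, the p53 target and DNA replication lists were lower, with medians of -0.33 and -0.10 (adjusted p = 0.0853 and 0.0692 with an estimated correlation). Of the 14 genes raised by BET inhibitors, 3 were lower and 0 higher (3 and 0 adjusted over the list alone), HEXIM1 and ZCCHC24 (-1.30 ± 0.22) among them. Their median was -0.00, their mean -0.21, and the test pointed down (adjusted p = 0.0308, and adjusted p = 0.426 with an estimated correlation). Single libraries ended the cholesterol (DMSO replicate 1, adjusted p = 0.0904, and pacritinib replicate 2, adjusted p = 0.134) and BET calls (pacritinib replicate 2, adjusted p = 0.0668). The other 11 lists did not pass (adjusted p = 0.136 to 0.834).

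Itacitinib at 4 h left the JAK-STAT feedback genes near DMSO. Not called were PIM1 (-0.05 ± 0.05, adjusted p = 0.831), CISH (0.13 ± 0.07, adjusted p = 0.543), SOCS3 (0.01 ± 0.12, adjusted p = 0.992) and DUSP6 (-0.15 ± 0.12, adjusted p = 0.697), which does not show that they were unaffected. Most called genes were higher, led by noncoding RNAs. Among them, MT-RNR1 (1.90 ± 0.30) lost its call without DMSO replicate 2 (adjusted p = 0.0597) and without itacitinib replicate 2 (adjusted p = 0.081). MT-RNR2 (1.38 ± 0.24) lost its call without DMSO replicate 2 (adjusted p = 0.185) and without itacitinib replicate 2 (adjusted p = 0.276). NEAT1 (1.03 ± 0.14) lost its call without itacitinib replicate 2 (adjusted p = 0.0567). Of the lower genes, ETV5 (-0.50 ± 0.07) lost its call without itacitinib replicate 2 (adjusted p = 0.081). GP6 (-0.37 ± 0.08) lost its call whichever of the 4 libraries was left out (adjusted p = 0.118 to 0.2). TBXA2R (-0.40 ± 0.08) lost its call without DMSO replicate 2 (adjusted p = 0.234) and without itacitinib replicate 2 (adjusted p = 0.243). By edgeR, 108 genes were higher and 17 lower than in DMSO (1735 at an unadjusted p under 0.05). The total of 125 became 39 without DMSO replicate 1, 20 without DMSO replicate 2, 196 without itacitinib replicate 1 and 2 without itacitinib replicate 2. Lists passed with the preset correlation only: the JAK-STAT target, ERK pathway output, ribosome biogenesis, ATF4 stress response and cholesterol synthesis lists were lower, with medians of -0.10, -0.16, -0.06, -0.05 and -0.06 (adjusted p = 0.267, 0.267, 0.267, 0.36 and 0.36 with an estimated correlation). The ribosome (adjusted p = 0.0845), ATF4 (adjusted p = 0.131) and cholesterol (adjusted p = 0.202) calls ended without DMSO replicate 2. The latter pair also ended without itacitinib replicate 2 (adjusted p = 0.0683 and 0.121). The other 15 lists did not pass (adjusted p = 0.0539 to 0.804).

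Genes called with each of the 5 inhibitors at 4 h were counted, and the mean of the 5 was tested, which 1 compound can carry. The 7 genes higher with each included MT-RNR1 (0.82 to 2.55), ST8SIA1 (0.55 to 1.24) and NEAT1 (0.46 to 1.03). Lower with each were 11 genes, among them the platelet receptor genes TBXA2R (0.40 to 1.27) and GP6 (0.37 to 1.51) and the ERK-responsive ETV5 (0.37 to 1.20), in absolute log2 fold change. All comparisons at 4 h shared the same DMSO libraries. In 20 simulations with a shared control and no effect 0 genes were common to all 5, but no group had over 2 calls, so a shift in the DMSO libraries is not excluded. The total of 18 became 1 without itacitinib replicate 2, 6 without DMSO replicate 2 and 11 without fedratinib replicate 1. In the mean of the 5 inhibitors, SOCS3 (-1.06 ± 0.09), PIM1 (-0.50 ± 0.04), CISH (-0.55 ± 0.06) and PIM2 (-0.91 ± 0.04) were lower, and so were DUSP6 (-1.12 ± 0.09), EGR1 (-0.88 ± 0.09), BCL3 (-1.41 ± 0.10) and HEXIM1 (-0.34 ± 0.04). HEXIM1 was at -1.78 with pacritinib and 0.08 with ruxolitinib, and SOCS3 at 0.01 with itacitinib. JAK2 (0.17 ± 0.04) lost its call without DMSO replicate 1 (adjusted p = 0.0516) and without DMSO replicate 2 (adjusted p = 0.233). MYC (-0.12 ± 0.03) lost its call without DMSO replicate 1 (adjusted p = 0.105) and without DMSO replicate 2 (adjusted p = 0.156). CCND2 (-0.15 ± 0.04) lost its call without DMSO replicate 1 (adjusted p = 0.0925) and without DMSO replicate 2 (adjusted p = 0.157). HMGCS1 (-0.18 ± 0.05) lost its call without DMSO replicate 1 (adjusted p = 0.119) and without DMSO replicate 2 (adjusted p = 0.0939). For the mean, 508 genes were higher and 986 lower than in DMSO, a total of 1494 that became 747 without DMSO replicate 1 and 485 without DMSO replicate 2.

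After 48 h, ruxolitinib had raised the haemoglobin programme. Globin genes were up (HBZ (2.38 ± 0.14), HBA2 (2.26 ± 0.10), HBA1 (1.82 ± 0.10) and HBG2 (0.72 ± 0.06)), with the haem synthesis enzyme ALAS2 (1.90 ± 0.08) and the red cell pyruvate kinase PKLR (1.95 ± 0.09). HBZ went from 6.46 ± 1.69 to 33.5 ± 1.55 CPM (mean ± SD). ERK-dependent transcripts were far below DMSO, led by CCND1 (-5.34 ± 0.36), ETV4 (-4.18 ± 0.16), DUSP6 (-3.37 ± 0.15) and ETV5 (-3.19 ± 0.10). JAK-STAT targets stayed down, with SOCS1 (-1.77 ± 0.19), SOCS3 (-1.69 ± 0.13), ID1 (-1.35 ± 0.08), PIM1 (-0.69 ± 0.05) and CISH (-0.33 ± 0.08). Platelet genes split, as GP6 (-2.36 ± 0.10) and SELP (-1.41 ± 0.08) were lower and TUBB1 (1.60 ± 0.09) was higher. JAK2 (0.71 ± 0.05) and the erythropoietin receptor gene EPOR (1.00 ± 0.07) rose. Lower were IL4R (-1.67 ± 0.12), BCL2L1 (-0.46 ± 0.04) and CCND2 (-1.12 ± 0.05) and, among the largest changes, IGFBP4 (-2.95 ± 0.14), SLC34A1 (-2.72 ± 0.16) and PLCH1 (-2.53 ± 0.08). SOCS2 (-0.38 ± 0.09) lost its call without ruxolitinib replicate 2 (adjusted p = 0.0672). HMGCS1 (-0.18 ± 0.06) lost its call without DMSO replicate 2 (adjusted p = 0.412) and without ruxolitinib replicate 2 (adjusted p = 0.263). MYC (0.10 ± 0.04) lost its call whichever of the 4 libraries was left out (adjusted p = 0.0837 to 0.32). By edgeR, 2011 genes were higher and 2126 lower than in DMSO, and 133 of the higher and 309 of the lower genes changed at least 2-fold. The total of 4137 became 2733 without ruxolitinib replicate 2.

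With ruxolitinib at 48 h, 31 of the 33 erythroid genes were higher and 0 lower (31 and 0 adjusted over the list alone). Their median was 0.69 (list adjusted p = 1.81e-65, and adjusted p = 1.99e-05 with an estimated correlation). 14 of the 18 ERK pathway output genes were lower and 0 higher (15 and 0 adjusted over the list alone). Their mean was -1.45 (list adjusted p = 2.85e-33, and adjusted p = 0.000241 with an estimated correlation). In the JAK-STAT target list, 15 of 23 genes were lower and 2 higher (19 and 2 adjusted over the list alone, median -0.38, adjusted p = 0.00236 with an estimated correlation). In the BMP-SMAD target list, 4 of 9 genes were lower and 1 higher (4 and 1 adjusted over the list alone, median -0.46, adjusted p = 0.0313 with an estimated correlation). The BMP-SMAD targets ID3 (-1.31 ± 0.12) and ID2 (-0.82 ± 0.11) were lower and SMAD6 (0.38 ± 0.06) higher. With the preset correlation only, the megakaryocyte and platelet, ribosome biogenesis, ATF4 stress response and cholesterol synthesis lists were lower, with medians of -0.28, -0.18, -0.27 and -0.19 (adjusted p = 0.0512, 0.0611, 0.091 and 0.0867 with an estimated correlation). The mitochondrially encoded list was higher on the same terms, with a median of 0.41 (adjusted p = 0.418 with an estimated correlation). The other 11 lists did not pass (adjusted p = 0.0582 to 0.796). Among these were markers of other blood cells, with 5 of 12 monocyte and granulocyte genes lower and 1 higher (5 and 1 adjusted over the list alone, adjusted p = 0.0634). In the lymphocyte marker list, 5 of 10 were lower and 1 higher (6 and 1 adjusted over the list alone, adjusted p = 0.0582).

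With fedratinib at 48 h, ATF4 stress genes lay above DMSO. In DMSO CHAC1 and DDIT4 fell from 4 h, so a smaller fall with fedratinib stays open. CHAC1 was higher (1.78 ± 0.17), with PHGDH (1.02 ± 0.07), ASNS (0.95 ± 0.12) and DDIT4 (1.10 ± 0.12). Globin genes rose too (HBZ (1.39 ± 0.14), HBA2 (1.31 ± 0.10) and HBA1 (1.15 ± 0.10)), whereas the sterol genes INSIG1 (-0.66 ± 0.06) and DHCR7 (-0.34 ± 0.06) fell. Of the JAK-STAT targets, BCL2L1 was slightly higher (0.22 ± 0.04), and PIM1 (-0.04 ± 0.05, adjusted p = 0.73) and SOCS3 (-0.12 ± 0.12, adjusted p = 0.623) were not called. EGR1 was higher (0.96 ± 0.12), and AHNAK (-0.98 ± 0.15), EPSTI1 (-0.98 ± 0.11), IGFBP4 (-0.97 ± 0.12) and KIT (-0.65 ± 0.06) were lower. HBG2 (0.26 ± 0.06) lost its call without DMSO replicate 2 (adjusted p = 0.0745) and without fedratinib replicate 1 (adjusted p = 0.305). HMGCS1 (-0.26 ± 0.06) lost its call without DMSO replicate 2 (adjusted p = 0.199) and without fedratinib replicate 1 (adjusted p = 0.0561). By edgeR, 588 genes were higher and 650 lower than in DMSO, and 20 of the higher and 40 of the lower genes changed at least 2-fold. The total of 1238 became 605 without DMSO replicate 1, 403 without DMSO replicate 2 and 355 without fedratinib replicate 1. Of the lists, 16 of the 25 ATF4 stress response genes were higher and 0 lower (19 and 0 adjusted over the list alone). Their median was 0.46 (list adjusted p = 1.66e-38, and adjusted p = 0.000399 with an estimated correlation). In the erythroid list, 11 of 33 genes were higher and 0 lower (16 and 3 adjusted over the list alone, median 0.10, adjusted p = 0.0205 with an estimated correlation). In the cholesterol synthesis list, 11 of 24 genes were lower (12 adjusted over the list alone, median -0.17, adjusted p = 0.016 with an estimated correlation). In the mitosis list, 6 of 26 genes were lower (13 adjusted over the list alone, median -0.11, adjusted p = 0.0205 with an estimated correlation). In the lymphocyte marker list, 3 of 10 genes were lower (4 adjusted over the list alone, median -0.41, adjusted p = 0.016 with an estimated correlation). In the interferon-stimulated list, 4 of 30 genes were lower and 1 higher (4 and 1 adjusted over the list alone, median -0.13, adjusted p = 0.0394 with an estimated correlation). With the preset correlation only, the mitochondrially encoded, BET-raised and BCL2 family lists were higher, with medians of 0.51, 0.21 and 0.09 (adjusted p = 0.102, 0.0849 and 0.0821 with an estimated correlation). The NF-kB target, monocyte and granulocyte and BMP-SMAD target lists were lower on those terms, with medians of -0.21, -0.13 and -0.18 (adjusted p = 0.112, 0.0849 and 0.102 with an estimated correlation). Without DMSO replicate 1 the interferon call ended (adjusted p = 0.0785). Without DMSO replicate 2 the monocyte (adjusted p = 0.167), BMP-SMAD (adjusted p = 0.0839) and BCL2 calls (adjusted p = 0.0837) did. Fedratinib replicate 1 decided the interferon (adjusted p = 0.0501), monocyte (adjusted p = 0.115) and BCL2 calls (adjusted p = 0.0613), and replicate 2 the BMP-SMAD call (adjusted p = 0.251). The other 8 lists did not pass (adjusted p = 0.191 to 0.747).

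Momelotinib at 48 h lowered the cholesterol synthesis and mitosis lists. The sterol genes INSIG1 (-0.59 ± 0.06) and HMGCS1 (-0.39 ± 0.06) were below DMSO, as were the ERK-responsive CCND1 (-1.51 ± 0.23), ETV4 (-0.73 ± 0.11) and DUSP6 (-0.73 ± 0.11). Other lower genes were PLCH1 (-0.54 ± 0.07) and IL1B (-0.54 ± 0.08), and CYP26B1 (0.81 ± 0.12) and DLK1 (0.63 ± 0.09) were higher. The JAK-STAT targets PIM1 (-0.01 ± 0.05, adjusted p = 0.957) and SOCS3 (0.13 ± 0.12, adjusted p = 0.646) were not called. By edgeR, 160 genes were higher and 152 lower than in DMSO, and 4 of the higher and 4 of the lower genes changed at least 2-fold. The total of 312 became 58 without DMSO replicate 1, 49 without DMSO replicate 2, 25 without momelotinib replicate 1 and 77 without momelotinib replicate 2. In the cholesterol synthesis list, 10 of 24 genes were lower (13 adjusted over the list alone, median -0.22, adjusted p = 0.00372 with an estimated correlation). In the mitosis list, 3 of 26 genes were lower (13 adjusted over the list alone, median -0.13, adjusted p = 0.00372 with an estimated correlation). With the preset correlation only, the ERK pathway output, BET-raised and ribosome biogenesis lists were lower, with medians of -0.15, -0.12 and -0.06 (adjusted p = 0.0969, 0.24 and 0.193 with an estimated correlation). The mitochondrially encoded, erythroid and lysosome lists were higher on those terms, with medians of 0.21, 0.03 and 0.05 (adjusted p = 0.46, 0.24 and 0.24 with an estimated correlation). The lysosome call ended without DMSO replicate 2 (adjusted p = 0.172) or momelotinib replicate 2 (adjusted p = 0.169). The other 12 lists did not pass (adjusted p = 0.122 to 0.968).

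Pacritinib at 48 h left ATF4 stress genes above DMSO, where CHAC1 fell from 4 h, so a smaller fall stays open. Higher were CHAC1 (1.54 ± 0.18), PHGDH (1.21 ± 0.07), PCK2 (0.94 ± 0.09) and ASNS (0.82 ± 0.12). The BMP-SMAD targets ID3 (-2.01 ± 0.13), ID2 (-1.47 ± 0.12), ID1 (-0.61 ± 0.07) and BAMBI (-0.62 ± 0.08) were lower, as were the ERK-responsive CCND1 (-2.11 ± 0.25), DUSP6 (-1.18 ± 0.12) and ETV4 (-0.86 ± 0.11). Platelet genes fell (SELP (-0.94 ± 0.08), GP6 (-0.80 ± 0.08) and GP1BA (-0.63 ± 0.06)), and so did HEXIM1 (-1.03 ± 0.06) and INSIG1 (-0.63 ± 0.06). Of the JAK-STAT targets, the cytokine gene OSM (1.35 ± 0.17) and CISH (0.43 ± 0.07) were above DMSO. SOCS3 was higher too (0.46 ± 0.12), a call lost without DMSO replicate 1 (adjusted p = 0.0956). Among the largest changes, SEMA3C (1.06 ± 0.11) and YBEY (1.04 ± 0.14) were higher and IGFBP4 (-1.88 ± 0.13), KDR (-1.77 ± 0.11) and NTS (-1.64 ± 0.12) lower. SOCS2 (0.31 ± 0.08) lost its call without DMSO replicate 2 (adjusted p = 0.0786) and without pacritinib replicate 2 (adjusted p = 0.165). PIM1 (0.15 ± 0.05) lost its call whichever of the 4 libraries was left out (adjusted p = 0.116 to 0.238). CCND2 (-0.19 ± 0.05) lost its call without pacritinib replicate 1 (adjusted p = 0.125). By edgeR, 1328 genes were higher and 1620 lower than in DMSO, and 93 of the higher and 75 of the lower genes changed at least 2-fold. The total of 2948 became 1851 without DMSO replicate 1, 1647 without DMSO replicate 2 and 1492 without pacritinib replicate 1. Of the lists, 18 of the 25 ATF4 stress response genes were higher and 0 lower (19 and 0 adjusted over the list alone). Their median was 0.39 (list adjusted p = 4.96e-25, and adjusted p = 0.00107 with an estimated correlation). In the BMP-SMAD target list, 5 of 9 genes were lower (5 adjusted over the list alone, median -0.61, adjusted p = 0.000703 with an estimated correlation). In the megakaryocyte and platelet list, 14 of 26 genes were lower and 2 higher (17 and 4 adjusted over the list alone, median -0.30, adjusted p = 0.000752 with an estimated correlation). In the mitosis list, 11 of 26 genes were lower (17 adjusted over the list alone, median -0.15, adjusted p = 0.017 with an estimated correlation). In the cholesterol synthesis list, 10 of 24 genes were lower (18 adjusted over the list alone, median -0.22, adjusted p = 0.0244 with an estimated correlation). With the preset correlation only, the mitochondrially encoded and erythroid lists were higher, with medians of 0.60 and 0.13 (adjusted p = 0.118 and 0.238 with an estimated correlation). The ERK pathway output, BET-raised and NF-kB target lists were lower on those terms, with medians of -0.31, -0.14 and -0.10 (adjusted p = 0.0688, 0.111 and 0.176 with an estimated correlation). Without pacritinib replicate 1 the erythroid (adjusted p = 0.0626) and NF-kB calls (adjusted p = 0.108) ended. The other 10 lists did not pass (adjusted p = 0.146 to 0.986). Of the 23 JAK-STAT targets, 5 were higher and 5 lower (5 and 5 adjusted over the list alone, adjusted p = 0.986).

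Itacitinib at 48 h again changed the fewest genes. Genes called lower included INSIG1 and CCND1, and the embryonic globin gene HBZ was called higher, but each call named here rested on single libraries. INSIG1 (-0.41 ± 0.06) lost its call without itacitinib replicate 2 (adjusted p = 0.217). HMGCS1 (-0.25 ± 0.06) lost its call whichever of the 4 libraries was left out (adjusted p = 0.0782 to 0.47). CCND1 (-1.04 ± 0.22) lost its call without DMSO replicate 1 (adjusted p = 0.262), without DMSO replicate 2 (adjusted p = 0.093) and without itacitinib replicate 2 (adjusted p = 0.461). DUSP6 (-0.50 ± 0.11) lost its call without DMSO replicate 1 (adjusted p = 0.198), without DMSO replicate 2 (adjusted p = 0.253) and without itacitinib replicate 2 (adjusted p = 0.517). IGFBP4 (-0.67 ± 0.11) lost its call without DMSO replicate 1 (adjusted p = 0.124) and without itacitinib replicate 2 (adjusted p = 0.277). HBZ (0.73 ± 0.14) lost its call without DMSO replicate 2 (adjusted p = 0.323) and without itacitinib replicate 2 (adjusted p = 0.277). By edgeR, 14 genes were higher and 57 lower than in DMSO (1803 at an unadjusted p under 0.05). The total of 71 became 3 without DMSO replicate 1, 11 without DMSO replicate 2 and 0 without itacitinib replicate 2. In the cholesterol synthesis list, 4 of 24 genes were lower (12 adjusted over the list alone, median -0.17, adjusted p = 0.0149 with an estimated correlation). With the preset correlation only, the mitochondrially encoded and erythroid lists were higher, with medians of 0.50 and 0.06 (adjusted p = 0.0686 and 0.0825 with an estimated correlation). The ERK pathway output, mitosis, DNA replication, megakaryocyte and platelet, ATF4 stress response and ribosome biogenesis lists were lower on those terms, with medians of -0.14, -0.07, -0.07, -0.07, -0.08 and -0.05 (adjusted p = 0.0825, 0.0686, 0.0686, 0.0686, 0.214 and 0.221 with an estimated correlation). The JAK-STAT list had a median of -0.08 and a mean of 0.002, and its test pointed down (adjusted p = 0.221 with an estimated correlation). Without itacitinib replicate 2 the JAK-STAT (adjusted p = 0.185) and megakaryocyte calls (adjusted p = 0.079) ended. The ribosome call ended without DMSO replicate 1 (adjusted p = 0.259) or itacitinib replicate 1 (adjusted p = 0.066). The other 10 lists did not pass (adjusted p = 0.0863 to 0.765).

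At 48 h, 16 genes were lower with all 5 inhibitors. They were led by IGFBP4 (0.50 to 2.95) and included the sterol regulator INSIG1 (0.41 to 0.66) and the neuropeptide gene NTS (0.40 to 1.64), in absolute log2 fold change. By edgeR 0 genes were higher with all 5, and DESeq2 gave 29 in both directions together. Simulations with a shared control and no effect gave 0, with at most 4 calls per group, which does not exclude a shift in DMSO either. The total of 16 became 2 without DMSO replicate 1, 3 without DMSO replicate 2, 7 without momelotinib replicate 1, and 0 without itacitinib replicate 2. In the mean of the 5 inhibitors, HBZ (1.05 ± 0.12), HBA2 (0.99 ± 0.08) and ALAS2 (0.70 ± 0.07) were higher, and ETV4 (-1.24 ± 0.09), CCND1 (-2.09 ± 0.18), DUSP6 (-1.17 ± 0.09) and INSIG1 (-0.59 ± 0.05) lower. PIM1 (-0.14 ± 0.04) lost its call without DMSO replicate 1 (adjusted p = 0.115) and without DMSO replicate 2 (adjusted p = 0.212). SOCS3 (-0.28 ± 0.09) lost its call without DMSO replicate 1 (adjusted p = 0.0857), without DMSO replicate 2 (adjusted p = 0.456), without itacitinib replicate 2 (adjusted p = 0.0562), without pacritinib replicate 1 (adjusted p = 0.0503) and without ruxolitinib replicate 2 (adjusted p = 0.0662). JAK2 (0.18 ± 0.04) lost its call without DMSO replicate 1 (adjusted p = 0.195). HBG2 (0.21 ± 0.05) lost its call without DMSO replicate 1 (adjusted p = 0.0571) and without DMSO replicate 2 (adjusted p = 0.0825). For the mean, 761 genes were higher and 1006 lower than in DMSO, a total of 1767 that became 695 without DMSO replicate 1 and 631 without DMSO replicate 2.

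**Figure D2:**
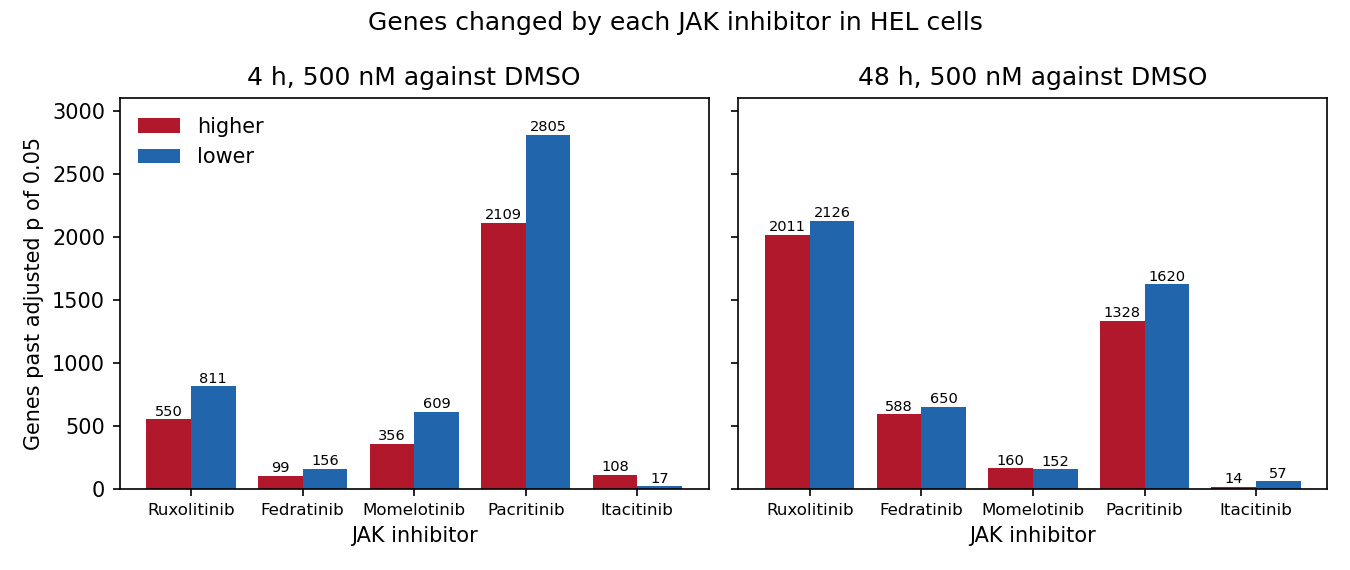
Genes higher and lower than DMSO (adjusted p under 0.05, counts) for each inhibitor and time. Pacritinib at 4 h had 2109 higher and 2805 lower, and itacitinib at 48 h had 14 and 57.

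**Figure D3:**
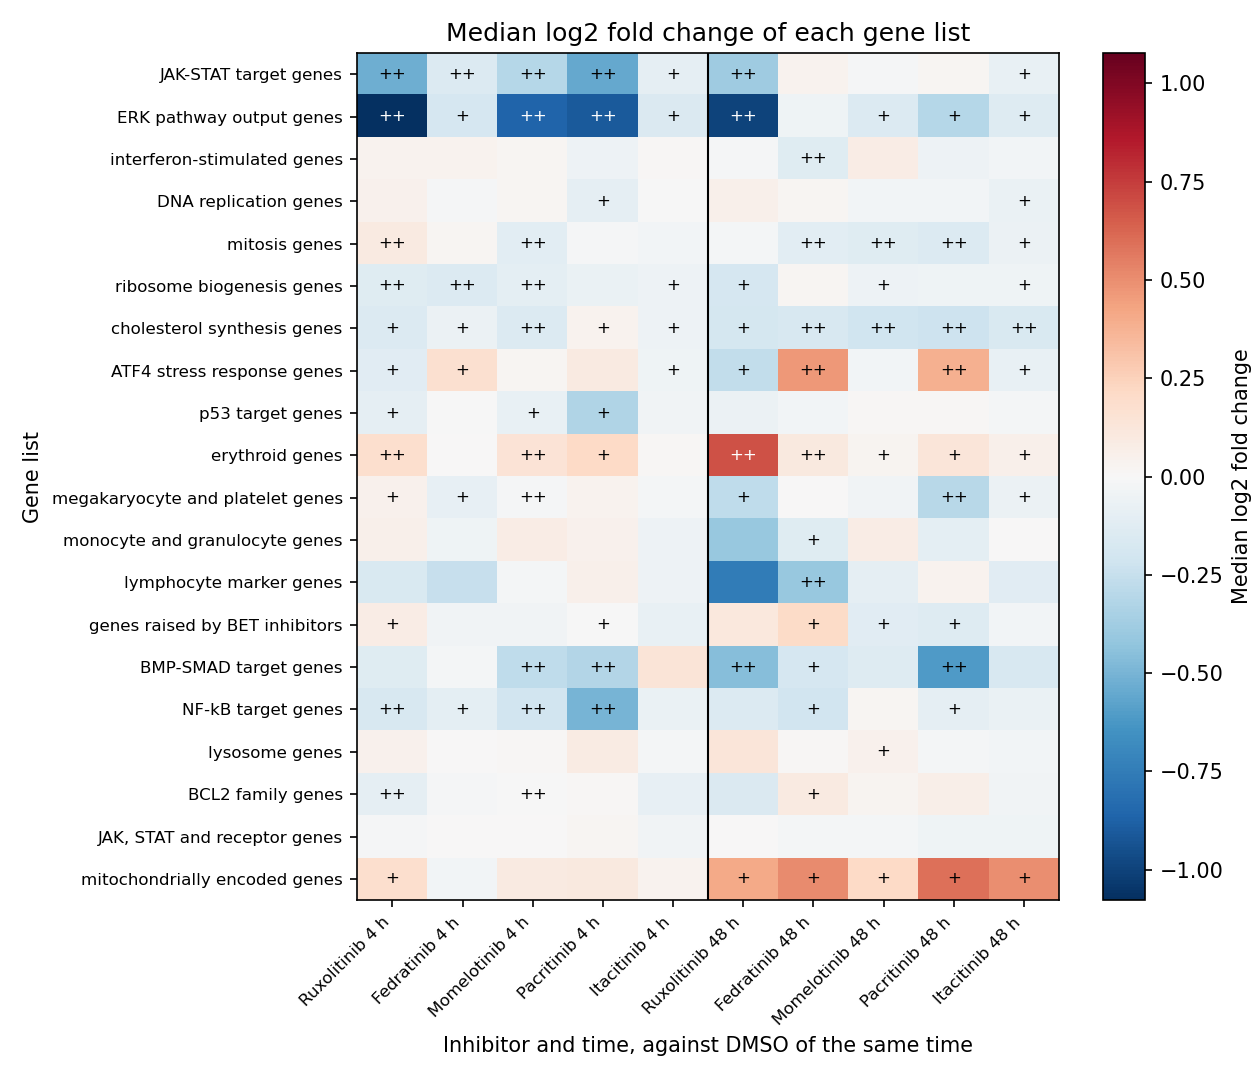
Median log2 fold change against DMSO of each gene list (colour) by inhibitor and time, where 1 plus sign marks a list past adjusted p 0.05 with the preset correlation and a second plus sign one past it with an estimated correlation too. The erythroid list reached 0.69 with ruxolitinib at 48 h, and the JAK-STAT list -0.53 with ruxolitinib and -0.55 with pacritinib at 4 h.

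DMSO at 48 h was compared with DMSO at 4 h, which may differ in batch too. Stress and immediate-early genes were lower at 48 h, with DDIT4 (-2.91 ± 0.11), JUN (-2.88 ± 0.09), PHLDA1 (-2.61 ± 0.13) and CHAC1 (-2.34 ± 0.17). Higher were MT-RNR1 (2.96 ± 0.30), MT-RNR2 (2.37 ± 0.25) and ABCG1 (0.90 ± 0.11). By edgeR, 649 genes were higher and 663 lower. The total of 1312 became 682 without DMSO replicate 1 and 494 without replicate 2 of 4 h, and 597 and 499 without those of 48 h. In the ATF4 stress response list, 16 of 25 genes were lower and 1 higher (20 and 1 adjusted over the list alone, median -0.34, adjusted p = 7.51e-05 with an estimated correlation). In the cholesterol synthesis list, 8 of 24 genes were higher (9 adjusted over the list alone, median 0.16, adjusted p = 0.0281 with an estimated correlation). In the BCL2 family list, 3 of 15 genes were lower (3 adjusted over the list alone, median -0.06, adjusted p = 0.0281 with an estimated correlation). With the preset correlation only, the JAK-STAT target, ERK pathway output, ribosome biogenesis, p53 target, NF-kB target and lysosome lists were lower, with medians of -0.12, -0.15, -0.06, -0.06, -0.04 and -0.07 (adjusted p = 0.211, 0.211, 0.211, 0.104, 0.104 and 0.181 with an estimated correlation). The BMP-SMAD target list was higher on those terms, with a median of 0.28 (adjusted p = 0.168 with an estimated correlation). The other 10 lists did not pass (adjusted p = 0.0511 to 0.976).

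Inhibitors were compared with each other at the same dose and time, in 10 pairs per time. At 4 h ruxolitinib held PIM1 lower than every other inhibitor did. The log2 differences (95% interval) were -1.54 (-1.65 to -1.42) from fedratinib, -1.34 (-1.46 to -1.23) from momelotinib, -1.44 (-1.56 to -1.33) from pacritinib and -1.65 (-1.76 to -1.53) from itacitinib. SOCS3 differed by -1.57 (-1.89 to -1.25) between ruxolitinib and momelotinib, and DUSP6 by -2.84 (-3.14 to -2.54) between ruxolitinib and fedratinib. Between pacritinib and itacitinib, HEXIM1 differed by -1.85 (-1.98 to -1.72). The difference between momelotinib and pacritinib did not pass for SOCS3 (0.19 (-0.09 to 0.46), adjusted p = 0.366) or DUSP6 (0.34 (0.05 to 0.62), adjusted p = 0.0855), which does not show that they acted alike. After 48 h, ruxolitinib was above pacritinib in JAK2 by 0.75 (0.65 to 0.86). HEXIM1 stayed lower with pacritinib than with itacitinib by -0.92 (-1.04 to -0.80).

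At 4 h, the pairs with pacritinib differed in the most genes: 4681 from itacitinib, 4610 from fedratinib, 4111 from ruxolitinib and 3331 from momelotinib. Ruxolitinib differed in 948 genes from itacitinib, 566 from fedratinib and 116 from momelotinib. Momelotinib differed in 443 from itacitinib and 226 from fedratinib, and fedratinib and itacitinib in 42. After 48 h, the pairs with ruxolitinib differed most: 3960 from pacritinib, 3521 from itacitinib, 3371 from momelotinib and 3309 from fedratinib. Pacritinib differed in 2510 from itacitinib, 1928 from fedratinib and 1297 from momelotinib. Fedratinib differed in 1074 from momelotinib and 955 from itacitinib, and momelotinib and itacitinib in 162.

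Genes of 1 inhibitor that differed from each of the other 4 in the same direction were counted, and such a gene need not differ from DMSO. Pacritinib at 4 h stood apart in 700 higher and 1327 lower genes. The lower ones were led by ID3 (1.74 to 1.91), HEXIM1 (1.52 to 1.93) and ZNF784 (1.21 to 1.52) and the higher ones by MS4A2 (1.12 to 1.45) and LRRN2 (0.90 to 1.07), in absolute log2 difference from the other 4. Ruxolitinib at 4 h stood apart in 14 higher and 38 lower genes, the latter led by SOCS3 (1.38 to 2.61), PIM1 (1.34 to 1.65) and CISH (1.19 to 1.90). After 48 h, it stood apart in 707 higher and 693 lower genes, with PKLR (1.55 to 1.74) and ALAS2 (1.33 to 1.69) higher and ETV4 (3.32 to 4.12) and ETV5 (2.59 to 3.11) lower. Pacritinib then had 130 higher and 192 lower, with LIF (0.64 to 3.37) higher and HEXIM1 (0.83 to 1.01) and ID3 (0.70 to 1.74) lower. Fedratinib at 48 h had 75 and 66, led by EGR1 (1.14 to 2.87) and HMCN1 (0.92 to 1.27). Momelotinib at 48 h had 22 higher, such as FLT4, and 1 lower, LMO2. Itacitinib had 13 higher and 0 lower at 4 h, with LIF at 0.27 and CISH at 0.13 against DMSO among the higher, and 5 and 11 at 48 h. At 4 h fedratinib had SLC1A4 and SESN2 higher and RIPOR3 lower, and momelotinib TTC14 higher. With 1 library left out, the totals fell as low as 996 for pacritinib and 20 for ruxolitinib at 4 h, and 908 for ruxolitinib, 115 for pacritinib and 66 for fedratinib at 48 h.

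**Figure D4:**
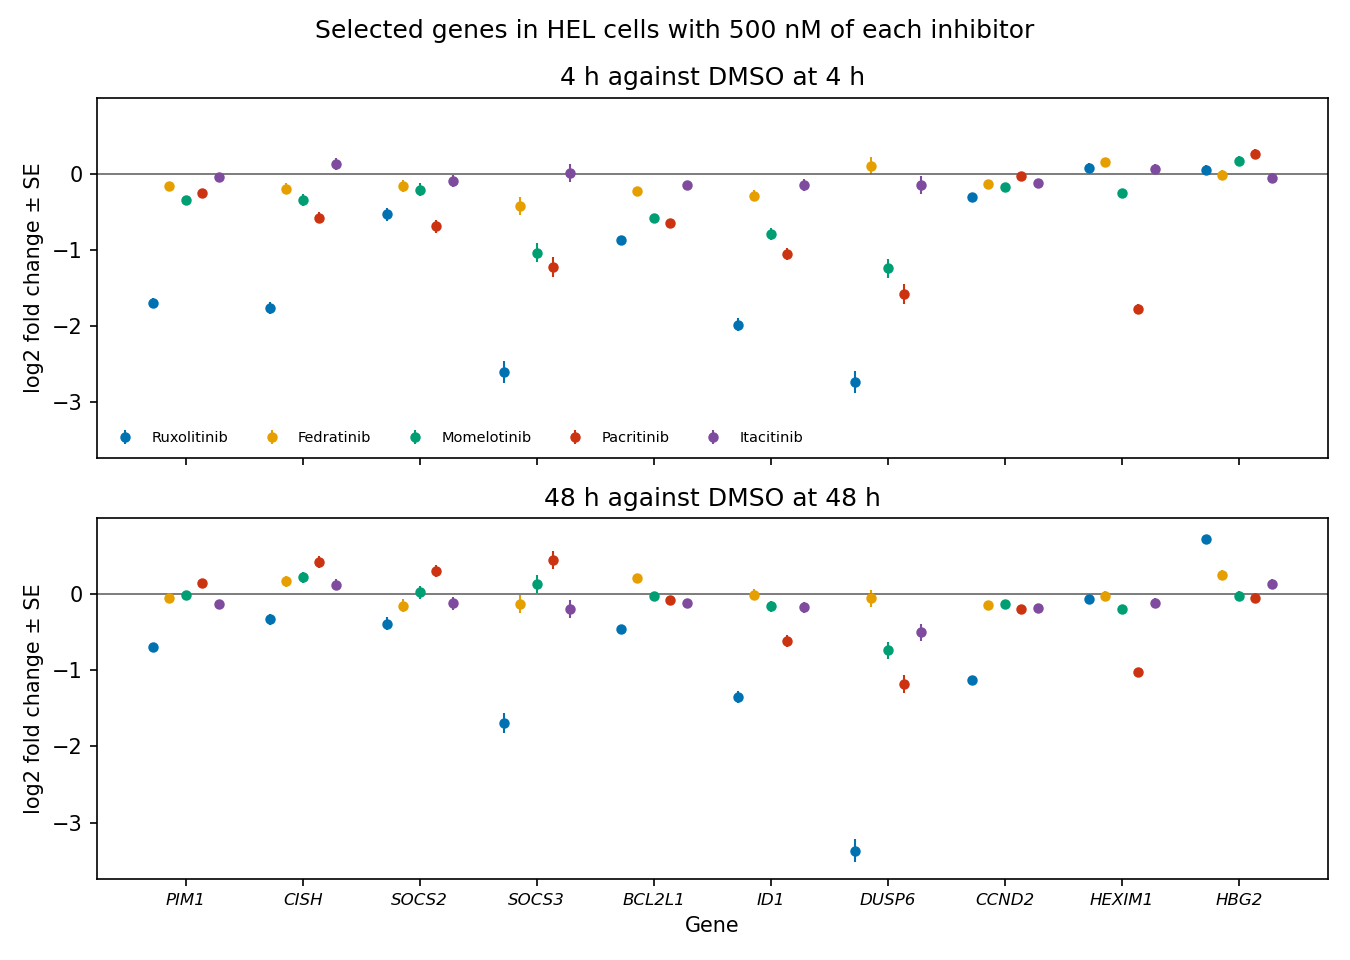
Log2 fold change against DMSO (± SE) of 10 genes named in advance, by inhibitor and time. PIM1 lay at -1.69 with ruxolitinib and -0.25 with pacritinib at 4 h, and HEXIM1 at -1.78 with pacritinib.

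The overlap between inhibitors was measured across genes, which are not independent replicates, in 20 pairs. Ruxolitinib and momelotinib at 4 h both lowered 465 genes and both raised 220, against 30.7 and 12.2 by chance and 0 in simulations with a shared control and no effect. Their fold changes correlated at r = 0.528, against a simulated 0.493 (0.451 to 0.527). The covariance was 0.106 (simulated 0.0689). Ruxolitinib and pacritinib at 4 h both lowered 568 and raised 236 (142 and 72.2 by chance, 0 simulated), while 58 changed in opposite directions. For this pair r was 0.377 (simulated 0.495) and the covariance 0.101 (simulated 0.0701, at most 0.0783). After 48 h they both lowered 721 and raised 585 (214 and 166 by chance, 0 simulated), with 217 opposite. At 48 h, r was 0.535 for momelotinib and itacitinib and 0.443 for ruxolitinib and momelotinib (simulated 0.537 and 0.5). Both covariances (0.0905, 0.1093) exceeded all simulated. Simulated groups had at most 2 calls at 4 h and 4 at 48 h, so 0 overlap does not exclude a DMSO shift. With each inhibitor set against another DMSO library, a check chosen after seeing the data, ruxolitinib and momelotinib at 4 h both lowered 238 or 235 genes in the 2 assignments (11.3 or 11.1 by chance), with a covariance of 0.0309 or 0.0311 and r = 0.08. Part of the overlaps given first may come from the shared control, and a shift common to both DMSO libraries stays open.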

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

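Whether the change against DMSO differed between 48 h and 4 h was tested for each inhibitor, as planned before the data were examined. With ruxolitinib it differed in 1402 genes, of which 36 were called in opposite directions at the 2 times. HBZ (2.09), HBA2 (1.99) and ALAS2 (1.69) differed upwards and ETV4 (-3.71) and IGFBP4 (-2.37) downwards, and BTG2 went from -0.42 to 0.60. With an estimated correlation 2 lists differed, the erythroid (adjusted p = 8.55e-05) and JAK-STAT lists (adjusted p = 0.021). With fedratinib it differed in 662 genes, 15 of them called in opposite directions. CHAC1 differed by 1.37, and of the 15, MT-RNR1 went from 2.00 to -1.08, MT-RNR2 from 1.57 to -0.78 and FOSL1 from -0.38 to 0.28. The calls of MT-RNR1 and FOSL1 at 48 h ended without DMSO replicate 2 (adjusted p = 0.232 and 0.354) and without fedratinib replicate 1 (adjusted p = 0.169 and 0.282). The reversal of MT-RNR1 and MT-RNR2 lay in DMSO, where they rose between the times (2.96 and 2.37), while their share of counts with fedratinib was 0.0504 and 0.0311% at 4 h and 0.0345 and 0.0436% at 48 h. With an estimated correlation 6 lists differed: the mitosis, ribosome and ATF4 lists (adjusted p = 0.0269 each), the interferon and BCL2 family lists (adjusted p = 0.036 each) and the JAK-STAT list (adjusted p = 0.0454).

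With momelotinib the change differed in 375 genes, 10 of them called in opposite directions. BCL3 (1.83), IL21R (1.61) and SOCS3 (1.17) differed upwards, and LIF, 1 of the 10, went from -0.46 to 0.76. The 3 lists that differed with an estimated correlation were the JAK-STAT (adjusted p = 0.000524), ERK (adjusted p = 0.0107) and BCL2 family lists (adjusted p = 0.0436). With pacritinib it differed in 2881 genes, 228 called in opposite directions. PHLDA1 differed by 2.22, but it fell in DMSO. Of the 228, SOCS3 went from -1.22 to 0.46 and FOSL1 from -1.13 to 0.43. The 3 lists were JAK-STAT (adjusted p = 0.00472), cholesterol and ATF4 (adjusted p = 0.0249 each). With itacitinib 2 genes differed by edgeR (1157 at an unadjusted p under 0.05, 13 by DESeq2), MT-RNR1 (-2.90) and MT-RNR2 (-2.13). This mirrors the rise in DMSO, as their share with itacitinib was 0.0292 and 0.0439% at 4 h and 0.0337 and 0.0501% at 48 h. MT-RNR2 was not called without DMSO replicate 2 of 48 h (adjusted p = 0.0513), itacitinib replicate 1 of 48 h (adjusted p = 0.0509) or itacitinib replicate 2 of 4 h (adjusted p = 0.0747). With itacitinib 0 genes were called in opposite directions and 0 lists differed with an estimated correlation. The lists that differed with the preset correlation were 5 with ruxolitinib, 12 with fedratinib, 6 with momelotinib, 11 with pacritinib and 3 with itacitinib.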

How the results depend on the processing

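Gene counts and named genes were recomputed with 1 choice changed at a time. Lists were not tested with DESeq2, nor comparisons between times on 1 time point only. Correlations across genes were recomputed only with RLE, without the genes called in the mean of the 5, with divided DMSO libraries and without single libraries. Counts of genes shared by pairs of inhibitors were recomputed only with divided DMSO libraries, and of genes called in opposite directions at the 2 times not at all. The cause of a changed result was not tested. No named gene with a call in the main fit changed direction, and genes without a call were not checked for this. With DESeq2, 1242 of the named gene results held, 56 were no longer called and 9 were called in addition; scaling by RLE changed 5. Without 1 library, 1221 gene results of single libraries were no longer called, against 6050 that held. Of the list results, 61 were no longer called with an estimated correlation and 55 held. Calls that ended were also 10 without the low-count filter, 7 with the stricter filter, 4 with protein-coding genes only, 2 on 1 time point only and 37 without single libraries, where 1 more reversed, while RLE and the block changed none. Without the filter these were the megakaryocyte (ruxolitinib and the mean of the 5, 4 h), BMP-SMAD (momelotinib and the mean, 4 h; fedratinib, 48 h), NF-kB (fedratinib, 4 h; pacritinib and the mean, 48 h), BET-raised (pacritinib, 4 h) and monocyte lists (fedratinib, 48 h). With the stricter filter they were the NF-kB (fedratinib, 4 h; pacritinib, 48 h), cholesterol (itacitinib and the mean, 4 h), BET-raised (pacritinib, 4 h), BMP-SMAD (fedratinib, 48 h) and ribosome lists (itacitinib, 48 h).

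With DESeq2 the gene counts that moved were 142 for itacitinib at 48 h, 13 for time difference of itacitinib, 131 for fedratinib against itacitinib at 4 h, 329 for momelotinib against itacitinib at 48 h and 8 for fedratinib apart at 4 h. Next were 2 for momelotinib apart at 4 h, 26 for itacitinib apart at 4 h, 29 for all 5 at 48 h and 28 for itacitinib apart at 48 h.

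With an estimated correlation between genes, the number of lists past the threshold was 7 for ruxolitinib at 4 h, 2 for fedratinib at 4 h, 4 for pacritinib at 4 h, 0 for itacitinib at 4 h, 4 for ruxolitinib at 48 h, 6 for fedratinib at 48 h, 2 for momelotinib at 48 h, 5 for pacritinib at 48 h, 1 for itacitinib at 48 h and 6 for the mean of the 5 at 48 h. With the genes called in the mean of the 5 left out, the correlation across genes was 0.477 for ruxolitinib and momelotinib at 4 h, 0.316 for ruxolitinib and pacritinib at 4 h, 0.507 for momelotinib and itacitinib at 48 h and 0.413 for ruxolitinib and momelotinib at 48 h. With DMSO replicate 1 for the first inhibitor and 2 for the second, and the reverse (chosen after seeing the data), it was 0.08 and 0.08 for ruxolitinib and momelotinib at 4 h, 0.062 and 0.085 for ruxolitinib and pacritinib at 4 h, 0.071 and 0.062 for momelotinib and itacitinib at 48 h and 0.102 and 0.09 for ruxolitinib and momelotinib at 48 h.

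Without the low-count filter, counts that moved were 416 for fedratinib at 4 h, 203 for itacitinib at 4 h, 189 for itacitinib at 48 h, 50 for time difference of itacitinib and 186 for ruxolitinib against momelotinib at 4 h. Next were 383 for fedratinib against momelotinib at 4 h, 247 for fedratinib against itacitinib at 4 h, 346 for momelotinib against itacitinib at 48 h, 32 for all 5 at 4 h and 16 for fedratinib apart at 4 h. Further values were 3 for momelotinib apart at 4 h, 41 for itacitinib apart at 4 h, 51 for all 5 at 48 h, 45 for momelotinib apart at 48 h and 56 for itacitinib apart at 48 h. Others were 8 for lists past the threshold with itacitinib at 4 h.

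With protein-coding genes only, an alternative chosen after seeing the data, counts that moved were 0 for time difference of itacitinib, 64 for fedratinib against itacitinib at 4 h, 6 for fedratinib apart at 4 h and 2 for momelotinib apart at 4 h. The stricter filter gave 5 for fedratinib apart at 4 h and 2 for momelotinib apart at 4 h.

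Fitted on the libraries of 1 time point only, the counts were 110 for fedratinib at 4 h, 55 for itacitinib at 4 h, 533 for momelotinib at 48 h, 145 for itacitinib at 48 h and 60 for ruxolitinib against momelotinib at 4 h. Next were 136 for fedratinib against momelotinib at 4 h, 16 for fedratinib against itacitinib at 4 h, 274 for momelotinib against itacitinib at 4 h, 432 for momelotinib against itacitinib at 48 h and 30 for ruxolitinib apart at 4 h. Further values were 0 for momelotinib apart at 4 h, 3 for itacitinib apart at 4 h, 42 for all 5 at 48 h, 46 for momelotinib apart at 48 h and 65 for itacitinib apart at 48 h.

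With replicate number as a block, counts that moved were 7 for fedratinib apart at 4 h and 2 for momelotinib apart at 4 h. A check for pairing by replicate number found a median correlation of 0.062 over 15 pairs at 4 h (lowest -0.346, highest 0.38) and -0.001 at 48 h (lowest -0.134, highest 0.164), with 6 pairs over 0.1 at 4 h and 2 at 48 h. Among ruxolitinib, fedratinib, momelotinib and pacritinib at 4 h it was 0.119 to 0.38, and of itacitinib with these -0.346 to -0.106, so a structure shared by some groups at 4 h stays open. Not every pair was over 0.1, so the numbers were not taken to pair the libraries.

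The library left out (treatment, replicate) is in brackets below. At 4 h, genes changed against DMSO ranged from 730 (DMSO 2) to 883 (DMSO 1) for ruxolitinib, 39 (DMSO 2) to 154 (DMSO 1) for fedratinib, 453 (DMSO 2) to 759 (momelotinib 1) for momelotinib, 3237 (pacritinib 2) to 3980 (pacritinib 1) for pacritinib and 2 (itacitinib 2) to 196 (itacitinib 1) for itacitinib. Next were 485 (DMSO 2) to 1659 (momelotinib 1) for the mean of the 5 and 1 (itacitinib 2) to 20 (itacitinib 1 or momelotinib 2) for all 5. At 48 h, genes changed against DMSO ranged from 2733 (ruxolitinib 2) to 3055 (ruxolitinib 1) for ruxolitinib, 355 (fedratinib 1) to 950 (fedratinib 2) for fedratinib, 25 (momelotinib 1) to 77 (momelotinib 2) for momelotinib, 1492 (pacritinib 1) to 2185 (pacritinib 2) for pacritinib and 0 (itacitinib 2) to 70 (itacitinib 1) for itacitinib. Next were 631 (DMSO 2) to 1864 (fedratinib 2) for the mean of the 5 and 0 (itacitinib 2) to 19 (pacritinib 2) for all 5. At 4 h, genes that differed between inhibitors ranged from 209 (ruxolitinib 1) to 418 (fedratinib 1) for ruxolitinib and fedratinib, 28 (ruxolitinib 1) to 119 (momelotinib 1) for ruxolitinib and momelotinib, 2449 (pacritinib 2) to 3210 (pacritinib 1) for ruxolitinib and pacritinib, 402 (ruxolitinib 1) to 692 (itacitinib 1) for ruxolitinib and itacitinib and 91 (fedratinib 2) to 528 (momelotinib 2) for fedratinib and momelotinib. Next were 2904 (fedratinib 2) to 3776 (fedratinib 1) for fedratinib and pacritinib, 1 (itacitinib 2) to 124 (itacitinib 1) for fedratinib and itacitinib, 1645 (pacritinib 2) to 2754 (momelotinib 1) for momelotinib and pacritinib, 158 (itacitinib 2) to 461 (momelotinib 1) for momelotinib and itacitinib and 2790 (pacritinib 2) to 3868 (pacritinib 1) for pacritinib and itacitinib. At 48 h, genes that differed between inhibitors ranged from 2123 (ruxolitinib 2) to 2437 (fedratinib 2) for ruxolitinib and fedratinib, 2173 (momelotinib 2) to 2433 (momelotinib 1) for ruxolitinib and momelotinib, 2227 (ruxolitinib 2) to 2549 (itacitinib 2) for ruxolitinib and itacitinib, 449 (momelotinib 1) to 677 (fedratinib 2) for fedratinib and momelotinib and 1019 (pacritinib 1) to 1273 (pacritinib 2) for fedratinib and pacritinib. Next were 239 (fedratinib 1) to 755 (fedratinib 2) for fedratinib and itacitinib, 496 (pacritinib 1) to 981 (pacritinib 2) for momelotinib and pacritinib, 12 (itacitinib 2) to 57 (itacitinib 1) for momelotinib and itacitinib and 957 (pacritinib 1) to 1815 (pacritinib 2) for pacritinib and itacitinib. At 4 h, genes of 1 inhibitor apart from the other 4 ranged from 20 (ruxolitinib 1) to 51 (itacitinib 2) for ruxolitinib, 0 (itacitinib 2) to 11 (momelotinib 2) for fedratinib, 0 (ruxolitinib 1 or fedratinib 1 or fedratinib 2 or itacitinib 1) to 8 (momelotinib 1) for momelotinib, 996 (pacritinib 2) to 1797 (fedratinib 1) for pacritinib and 1 (itacitinib 2) to 29 (momelotinib 1) for itacitinib. At 48 h, genes of 1 inhibitor apart from the other 4 ranged from 908 (ruxolitinib 2) to 1301 (pacritinib 1) for ruxolitinib, 66 (fedratinib 1) to 120 (pacritinib 1) for fedratinib, 3 (itacitinib 2) to 21 (fedratinib 1) for momelotinib, 115 (pacritinib 1) to 264 (itacitinib 1) for pacritinib and 0 (momelotinib 1 or momelotinib 2) to 15 (pacritinib 2) for itacitinib. Genes changed with time in DMSO, or whose change differed with time, ranged from 909 (ruxolitinib 2 of 48 h) to 1113 (ruxolitinib 1 of 48 h) for ruxolitinib, 221 (fedratinib 1 of 48 h) to 701 (fedratinib 2 of 48 h) for fedratinib, 131 (DMSO 2 of 48 h) to 480 (momelotinib 1 of 4 h) for momelotinib, 1801 (pacritinib 2 of 4 h) to 2711 (pacritinib 1 of 4 h) for pacritinib, 1 (itacitinib 2 of 4 h) to 11 (itacitinib 1 of 4 h) for itacitinib and 494 (DMSO 2 of 4 h) to 682 (DMSO 1 of 4 h) for time in DMSO.

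For correlations across genes and lists, values without 1 library ranged from -0.086 (DMSO 2) to 0.444 (DMSO 1) for mitochondrially encoded genes, ruxolitinib at 4 h, 3 (DMSO 2) to 8 (itacitinib 1) for lists past the threshold with itacitinib at 4 h and 0.302 (ruxolitinib 2) to 0.751 (DMSO 2) for ruxolitinib and momelotinib at 4 h. Next were 0.207 (ruxolitinib 2) to 0.682 (DMSO 2) for ruxolitinib and pacritinib at 4 h, 0.377 (momelotinib 2) to 0.758 (DMSO 2) for momelotinib and itacitinib at 48 h and 0.313 (ruxolitinib 1) to 0.654 (DMSO 2) for ruxolitinib and momelotinib at 48 h.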

Other observations

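Of the tests below, those of gene length and of zinc finger genes were chosen before their results were seen. The tests of DMSO over time, pacritinib against itacitinib, scaling, library labels, the DMSO level at 4 h and loss of the compound were chosen only after the result was seen.

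MT-RNR1 was called higher with all 5 inhibitors at 4 h, though with itacitinib not without its replicate 2 (adjusted p = 0.081) or DMSO replicate 2 (adjusted p = 0.0597), and MT-RNR2 with 4 of them but not with pacritinib (0.32). Both were also higher in DMSO at 48 h than at 4 h, by a median of 2.67, so the DMSO libraries at 4 h may be low for a reason other than the missing inhibitor. MT-RNR1 was lower with pacritinib than with itacitinib (-1.08 ± 0.28, adjusted p = 0.00399) but highest with ruxolitinib (2.55). So JAK inhibition and opposing effects of pacritinib stay open.

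Pacritinib at 4 h stood apart from the other 4 in 2027 genes. Removing length and exon trends left 96.1 or 91.4% of their median absolute change. Lower genes were longer (38.2 kb) than higher ones (23.6 kb), so partial length bias stays open. TMM, RLE and DESeq2 centre most genes near 0, so the 0.016 between medians cannot test scaling. Lower output of new RNA cannot be told apart, as the 460 zinc finger genes had a median of -0.001 and went both ways. No batch is given in the labels.

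With pacritinib at 48 h, 5 of 23 JAK-STAT targets lay above DMSO and 5 below, and the calls of SOCS2, PIM1 and SOCS3 among the higher ended without single libraries. A fall in DMSO between the times is argued against for OSM, CISH and SOCS3, the lowest of which lay 0.317 above DMSO at 4 h, but may account for SOCS2 and PIM1 (0.004). A single wrongly labelled library from another group at 48 h is weakly argued against. Each pacritinib library lay at least 0.34 above the highest of the 10 others on genes picked without it. The other inhibitors helped pick these, and only 1 library lay nearest its replicate. Both being wrongly labelled cannot be told apart (-0.3 in the 6 lower genes furthest apart at 4 h). Loss of the compound stays open, with 26.1% of the median change of those 6 genes left, though ID3 (-2.01) and HEXIM1 (-1.03) stayed lower while MEPCE (-0.06) and RNF19B (-0.15) were near DMSO. A rebound after inhibition was not tested.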
